A study of Homo sapiens with 18 samples.

How the data were processed

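RNA sequencing libraries of the human pancreatic cancer line MiaPaCa-2 were analysed, 18 in all, in 6 groups of 3: the parental line, passage 1 laggers, and leaders of passages 1, 2, 3 and 4 of serial injection into the sciatic nerve. Complementary DNA was amplified from low-input RNA with the SMART-Seq v4 kit, which does not mark strand, and sequenced as paired 50-base reads, per the labels. The deposited file holds raw counts per gene, 1 column per library, which the authors made with cutadapt 1.6, STAR 2.5.0a and HTSeq 0.5.3, per the submitters' processing notes, which also name DESeq 1.22.1. The genome build and gene annotation are not given in the sources used here. Gene names, types, chromosomes, GC content and length were taken from GENCODE 29, which held 51488 of the 57445 gene identifiers. The values were whole numbers with gene totals that differed between libraries, as raw counts do.

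The file ended in 5 entries that name no gene, which were left out of the tests and kept as library measures. Together they took 27.6% to 60.6% of all entries. Reads aligned to more than one place took 13.9% to 16.4% in the parental libraries and 20.2% to 32.6% in the injected ones, unaligned reads 4.09% to 24.8%, ambiguous reads 1.60% to 2.92%, reads outside genes at most 8.8% except for 14.1% in passage 3 leader replicate 2, and the entry for low alignment quality was 0. Gene totals ran from 15113462 to 39373248 counts. Replicates of the same group were compared in pairs and were not identical within counting error: chi-square per degree of freedom was 21.4 to 242.

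Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with quasi-likelihood F tests on 1 fit of all 18 libraries with 1 mean per group. Library sizes were scaled by the trimmed mean of M-values (TMM). Genes were kept by the edgeR filter on expression, which left 16187 to test and 41258 not tested. P-values were adjusted by the Benjamini-Hochberg method within each of the 8 comparisons, and a gene was called changed at an adjusted p under 0.05. The common dispersion was 0.126, a biological coefficient of variation of 35.5%, with 12 residual and 4.25 prior degrees of freedom. The comparisons were passage 1 leaders against laggers, laggers and the leaders of each passage against the parental line, passage 4 against passage 1 leaders, and a linear trend over the 4 leader passages. Levels are CPM from TMM-scaled library sizes, and intervals for log2 fold changes are 95% intervals.

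Gene lists were fixed before the data were examined: 23 pathway lists and 5 lists of markers of other cell types that a nerve could hold. The pathway lists include nerve-invasion ligands and receptors, axon guidance, integrins and laminins, mesenchymal regulators, epithelial genes, matrix proteases, actin and motility, cell cycle, hypoxia and glycolysis, interferon response, antigen presentation, inflammatory cytokines and NF-kB, MAPK output, immediate early and stress genes, the integrated stress and unfolded protein response, YAP and TEAD, TGF-beta, and Notch and Wnt targets, cholesterol and fatty acid synthesis, nuclear and mitochondrial genes of oxidative phosphorylation, and drug efflux and oxidative defence. Each list was tested with camera of limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 28 lists, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

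Named genes followed a rule set with the lists. For passage 1 leaders against laggers, laggers and passage 1 and 4 leaders against the parental line, and the trend, the 10 largest changes in each direction were named among called genes with at least 5 CPM in the higher group, no overlap between replicates and a symbol that is not a clone name. From each list up to 4 members with the smallest adjusted p were named, members that did not pass could be named with their values, and CDKN2A, VIM, CDH1, EPCAM, KRT8 and KRT18 were read as levels. Not every gene that the rule gave is named. MTAP, MEST, HBB, HBD, HBA1, HBA2 and CCDC73 were chosen after their values were seen, as were the examples given for genes with opposite changes at passages 1 and 4. A fold against a group with 0 counts is a lower bound that sets that group at 3 counts, and with 1 to 3 counts in the lower group or where a counting interval is printed the ratio carries a 95% interval for counting error alone. In a step added after the values were seen, these folds were computed again without the library of the higher group with the most counts for its size, and the text gives the new value where it is more than 1.5 times lower. The gene lists called with camera were also tested again without each compared library, another step added after the values were seen.

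The tests were tested on simulated data with the size of this experiment, in which 100 genes per fold were changed. For passage 1 leaders against laggers edgeR found 16% of 2-fold and 76% of 4-fold changes with 2.1% of calls false, DESeq2 1.42.0 found 30% and 85% with 19% false, and limma-voom 13% and 73% with 2.3% false. For passage 4 leaders against the parental line edgeR found 20% and 70% with 1.1% false, and for the trend 24% and 67% with 4.2% false. camera called the 1 list that was shifted and 0 of the other lists. The genes were simulated independently of each other, so this cannot show how camera behaves where genes of a list vary together.

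The alternatives were DESeq2, limma-voom, median-ratio normalization, no filter on low counts, a stricter filter of 1 CPM in at least 3 libraries, only the compared groups in the fit, the replicate number as a block, libraries thinned to 15113462 counts, and each library left out in turn. Offsets for GC content and length, the library with the largest unaligned share left out of each group, and mitochondrially encoded genes left out were added after the data were seen. For comparisons that share the parental libraries, all 18 libraries were simulated without change in 10 draws, each gene at its mean over all groups. The parental libraries were simulated too, so the observed control counts were not held fixed. Levels of genes that mark sex were not reported.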

Results

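Gene expression was measured by RNA sequencing in 18 libraries of MiaPaCa-2, an established line of human pancreatic cancer cells. The study asked how cells that travel farthest along a nerve differ from cells that stay behind, since pancreatic cancer spreads along nerves. Cells were injected into the sciatic nerve, and those recovered from the front were called leaders and those from the rear laggers. Leaders were grown in culture and injected again, over 4 passages. The 6 groups held 3 libraries each: the parental line, which was never injected, passage 1 laggers, and leaders of passages 1, 2, 3 and 4. Nothing states that the replicates of a group came from separate cultures or animals, so the p-values measure the spread between these samples, which can be technical. Whether RNA was taken directly at harvest or after regrowth in culture is not given in the sources used here, which leaves open what the stress and mitochondrial values below reflect.

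Counts assigned to genes ranged from 15113462 in lagger replicate 3 to 39373248 in parental replicate 1. The parental libraries held 29005147 to 39373248 counts, the laggers 15113462 to 21117967, and the leaders of passages 1, 2, 3 and 4 held 21474819 to 26110847, 20837228 to 27302253, 17743014 to 29140124 and 22301278 to 31980851. Levels are given in CPM, the edgeR measure of counts scaled to library size, as mean ± SD over 3 libraries, and log2 fold changes carry their standard error (SE). Intervals and floors given for low counts cover counting error only. For every gene named below as called over all genes by the per-gene test, all 3 replicates of one group lay beyond all 3 of the other (passages 1 and 4 for the trend), an order that chance gives for 10% of unchanged genes. The genes of largest change were named only if they had this order, so it is no support for them. Of the list members that the rule gave, 4 in laggers against the parental line had only 2 replicates beyond.

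Known features of the line were read as levels. MTAP, which was chosen after its values were seen and lies beside CDKN2A, had 0 counts in every library, and CDKN2A had 0 counts except for 6 in one lagger library. VIM, an intermediate filament of mesenchymal cells, averaged 1826 ± 35.4 CPM in the parental line and up to 2581 CPM in passage 2 leaders. Of the epithelial adhesion genes, CDH1 had 0 counts in the parental line and 8.68 ± 7.01 CPM in passage 1 leaders.

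The injected groups stood apart from the parental line in library make-up as well as in expression. Mitochondrially encoded genes took 0.686 ± 0.202% of gene counts in the parental line, 7.01 ± 1.32% in the laggers, and 6.80 ± 1.57%, 3.68 ± 0.289%, 3.07 ± 0.327% and 2.62 ± 0.692% in leaders of passages 1 to 4. Reads that aligned to more than one place made up 13.9% to 16.4% of entries in the parental libraries and 20.2% to 32.6% in the injected ones. The first principal component, with 33.8% of the variance, parted the parental libraries from all injected ones, and the second, with 17.7%, parted passage 1 from the later passages.

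**Figure D1:**
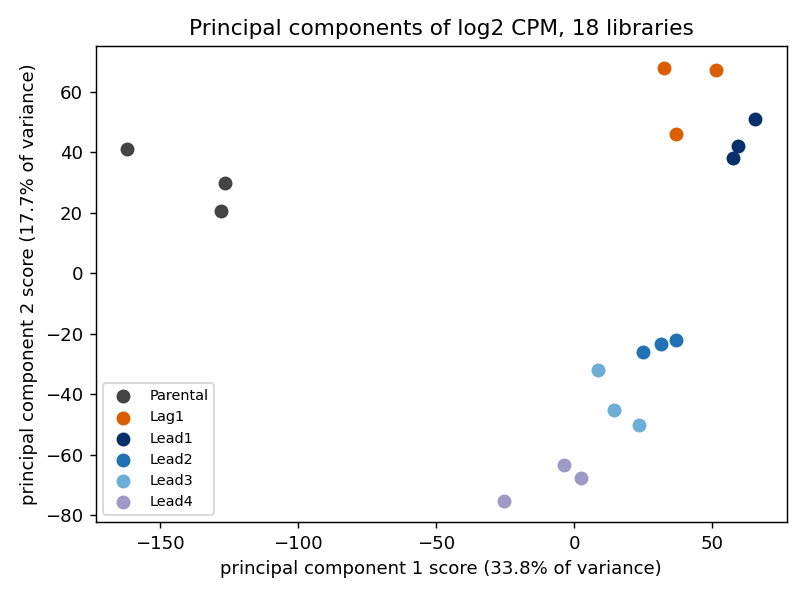
Principal components of log2 CPM for the 18 libraries, with the first component (33.8% of variance) on the horizontal axis and the second (17.7%) on the vertical axis, 1 point per library and 1 colour per group. The parental libraries lie at first-component scores of -162 to -126, and no injected library lies below -25.4.

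Leaders were compared with laggers of the same passage to find what parts cells at the front from cells at the rear. HSPA6, a heat shock protein induced by stress, fell from 1839 ± 714 CPM in laggers to 429 ± 126 CPM in leaders (log2 fold change -2.10 ± 0.36 SE, edgeR adjusted p = 0.0395). BAG3, a co-chaperone that works with heat shock proteins, fell from 649 ± 92.1 to 209 ± 31.3 CPM (-1.64 ± 0.21, edgeR adjusted p = 0.011). AMOTL2, a scaffold protein at cell junctions and a target of the regulator YAP, fell from 177 ± 43.9 to 41.9 ± 17.9 CPM (-2.08 ± 0.34, edgeR adjusted p = 0.0395). AGR2, a secretory pathway protein of epithelial tumours, rose from 0.557 ± 0.28 to 32.9 ± 26.3 CPM (5.90 ± 0.91, edgeR adjusted p = 0.0395). Its ratio from counts was 63.6, and 37.1 without leader replicate 3.

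In all, 10 of 16187 tested genes differed between passage 1 leaders and laggers, 3 of them higher in leaders and 7 lower, and 2338 had an unadjusted p under 0.05. The other 2 that rose were ERBB3, a receptor of the neuregulin growth factors and a member of the Schwann cell list (4.96 ± 0.84), which was lower in laggers than in the parental line (-5.44 ± 0.85), and GPX8, a peroxidase of the endoplasmic reticulum (1.39 ± 0.24). The ERBB3 ratio from counts was 28.8, and 13.3 without leader replicate 2. The others that fell were SPSB1 (-1.76 ± 0.30), the transcription factor RUNX1 (-1.36 ± 0.21), TRIM26 (-1.20 ± 0.18) and PARP3 (-1.15 ± 0.19). The count depended on single libraries. It was 52 without lagger replicate 1 (25 higher, 27 lower), 0 without lagger replicate 2 (2210 at an unadjusted p under 0.05), and 1 without lagger replicate 3. With edgeR it was 0, 3 and 0 without leader replicates 1, 2 and 3 (1882 and 1984 at an unadjusted p under 0.05 for the zeros). DESeq2 called 372 genes (191 higher, 181 lower), limma-voom 27 (8 higher, 19 lower) and edgeR with no filter on low counts 257 (162 higher, 95 lower). Without the libraries of largest unaligned share it called 11 (8 higher, 3 lower). The replicate block left 3, offsets for GC content and length 1, and a fit of only the compared groups 0 with edgeR (1289 at an unadjusted p under 0.05). The balance of higher and lower genes is therefore not settled. HSPA6 has a near-identical pseudogene, so its count is uncertain.

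Between leaders and laggers 7 gene lists passed with camera, none of them with an estimated correlation or with fry (fry adjusted p = 0.0515 to 0.152), and most members of 6 of the lists did not pass even over their list alone. Of 25 antigen presentation genes, 15 were lower when adjusted over the list alone, among them PSMB8, a subunit of the immunoproteasome, at -3.66 ± 0.95 (edgeR adjusted p = 0.125 over all genes). Its level in laggers came from 1 library, with 123 CPM in replicate 1 and 2.73 and 5.95 CPM in replicates 2 and 3. The list as a whole ranked low (camera adjusted p = 1.27e-07, and adjusted p = 0.368 with an estimated correlation). Of 36 interferon response genes, 7 were lower when adjusted over the list alone, with ISG15 at -1.94 ± 0.41 (edgeR adjusted p = 0.0755 over all genes; camera adjusted p = 0.000698, and adjusted p = 0.436 with an estimated correlation). Of 26 immediate early and stress genes, 9 were lower when adjusted over the list alone, with NR4A1 at -1.35 ± 0.28 and DNAJB1 at -0.94 ± 0.19 (edgeR adjusted p = 0.0755 for both over all genes; camera adjusted p = 1.27e-07, and adjusted p = 0.339 with an estimated correlation). Of 25 epithelial genes, 3 were higher when adjusted over the list alone, with CLDN1, a tight junction protein, at 1.05 ± 0.24 (edgeR adjusted p = 0.0902 over all genes; camera adjusted p = 2.85e-05, and adjusted p = 0.318 with an estimated correlation). Cholesterol and fatty acid synthesis ranked high (3 of 29 higher when adjusted over the list alone, HMGCS1 at 1.30 ± 0.29; camera adjusted p = 0.000698, and adjusted p = 0.339 with an estimated correlation), as did hypoxia and glycolysis (1 of 36 higher when adjusted over the list alone; camera adjusted p = 0.0381, and adjusted p = 0.509 with an estimated correlation). The YAP and TEAD target list ranked low (AMOTL2 passed over all genes, 1 of 21 when adjusted over the list alone; camera adjusted p = 0.0386, and adjusted p = 0.339 with an estimated correlation). Without lagger replicate 1 the antigen presentation list did not pass (camera adjusted p = 0.438; 3 lower and 3 higher over the list alone), nor did the interferon list (camera adjusted p = 0.692). Of the 7 lists, stress and epithelial genes kept their camera call without any 1 of the 6 libraries. Library measures parted the same groups: unaligned reads took 8.82% to 16.5% of entries in laggers and 7.04% to 7.57% in leaders, reads aligned to more than one place 27.8% to 32.6% and 22.9% to 27.4%. The mean correlation of a library with its replicates was 0.918 to 0.936 in laggers and 0.949 to 0.962 in leaders.

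Passage 1 laggers were compared with the parental line to measure what passage through the nerve changed in cells that did not lead. Immediate early regulators rose: NR4A2, an orphan nuclear receptor, went from 0.113 ± 0.0811 to 366 ± 56.7 CPM (log2 fold change 11.70 ± 0.40 SE, edgeR adjusted p = 2.86e-11), and FOS, a component of the AP-1 transcription factor, rose by 5.85 ± 0.32 (edgeR adjusted p = 1.02e-08). UCA1, a long noncoding RNA of epithelial cancers, fell from 366 ± 19.7 to 0.582 ± 0.446 CPM (-9.25 ± 0.67, edgeR adjusted p = 1.13e-07). RARRES2, which encodes the chemoattractant chemerin, rose from 0.0374 ± 0.0121 to 217 ± 190 CPM (12.32 ± 1.13, edgeR adjusted p = 1.18e-06); its ratio from counts was 6040, and 2780 without lagger replicate 2. In all 6363 genes differed, 3479 higher and 2884 lower in laggers, and 4608 of them by a log2 fold change of at least 1.

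Other genes that rose in laggers were near absent from the parental libraries. The interferon-induced GTPase gene GBP1 reached 39.0 ± 55.7 CPM against 1 parental count (ratio 4560, 95% counting interval 818 to 180000), and MS4A6A 32.6 ± 15.6 CPM (ratio 3460, 620 to 137000). SAMD9L was at least 642-fold higher, DKK4, a secreted Wnt inhibitor, 422-fold and EPHA3, an ephrin receptor, 370-fold, each as a lower bound against a floor of 3 counts over the parental group. CYP2B7P1, a pseudogene close in sequence to an expressed gene and therefore uncertain, was at least 523-fold higher. Single libraries carried much of this. Without lagger replicate 1 GBP1 was higher by a ratio of 693 and SAMD9L at least 53.5-fold, and without replicate 2 EPHA3 at least 224-fold and CYP2B7P1 at least 312-fold. Among genes that fell, the fatty acid elongase ELOVL2 changed by -7.07 ± 0.78, the hexokinase-like HKDC1 by -6.99 ± 1.13, the calcium channel subunit CACNG6 by -7.50 ± 0.91, GSG1 by -6.97 ± 0.91 and PEAR1 by -6.04 ± 0.89. BIRC7, an inhibitor of apoptosis, was lower by a ratio of 518 (92.8 to 20500) and CACNG7 by 350 (62.7 to 13900). The pregnancy-specific glycoproteins PSG4 (at least 127-fold lower) and PSG9 (-6.55 ± 1.09) fell too, and reads of this family cannot be assigned with certainty to single members.

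More stress, antigen presentation, interferon and mitochondrial genes were higher than lower in laggers against the parental line, and more cell cycle genes were lower. Of 26 immediate early and stress genes, 21 rose and 5 did not pass (22 rose and 1 fell when adjusted over the list alone, camera adjusted p = 6.02e-34, and adjusted p = 0.00981 with an estimated correlation). ATF3 changed by 5.51 ± 0.33 and NR4A1 by 5.31 ± 0.33 beside NR4A2 and FOS, and this list kept its call with an estimated correlation. Of 44 cell cycle genes, 36 fell and 8 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 2.19e-17, and adjusted p = 0.0891 with an estimated correlation). The proliferation marker MKI67 changed by -1.84 ± 0.21, the replication helicase MCM4 by -1.67 ± 0.18 and the mitotic kinase AURKA by -1.99 ± 0.24. Of 25 antigen presentation genes, 19 rose, 1 fell and 5 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 3.15e-06, and adjusted p = 0.301 with an estimated correlation). HLA-C rose from 47.3 ± 10.4 to 327 ± 162 CPM (2.79 ± 0.32), and PSMB9 by 4.48 ± 0.64. Lagger replicate 1 carried much of this: the PSMB9 ratio from counts was 24.6, and 7.42 without it, when 13 genes of the list rose and 1 fell (camera adjusted p = 6.88e-05, and adjusted p = 0.171 with an estimated correlation). Of 36 interferon response genes, 22 rose, 1 fell and 13 did not pass (26 and 1 when adjusted over the list alone, camera adjusted p = 5.84e-06, and adjusted p = 0.184 with an estimated correlation). BST2, an antiviral membrane protein, changed by 3.82 ± 0.51. All 13 mitochondrially encoded genes rose, also when adjusted over the list alone (camera adjusted p = 3.22e-22, and adjusted p = 0.0791 with an estimated correlation). MT-ND3 changed by 3.60 ± 0.29. Beside them 20 of 35 nuclear genes of oxidative phosphorylation rose while 4 fell (21 and 5 when adjusted over the list alone; camera adjusted p = 0.0029, and adjusted p = 0.544 with an estimated correlation).

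In the cytoskeletal, YAP and oxidative defence lists more genes fell than rose in laggers, and in the fibroblast list more rose. Of 21 YAP and TEAD targets, 11 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 8.42e-05, and adjusted p = 0.0791 with an estimated correlation). ASAP1, a regulator of focal adhesions, changed by -3.19 ± 0.21. Of 40 actin and motility genes, 18 fell and 9 rose (19 and 12 when adjusted over the list alone, camera adjusted p = 0.0114, and adjusted p = 0.27 with an estimated correlation; camera adjusted p = 0.064 without lagger replicate 1). The focal adhesion protein VCL changed by -2.91 ± 0.22 and the GTPase RHOB by 3.84 ± 0.29. Of 26 drug efflux and oxidative defence genes, 13 fell and 3 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.00253, and adjusted p = 0.0891 with an estimated correlation). Thioredoxin reductase TXNRD1 changed by -2.71 ± 0.30. Of 10 fibroblast markers, 6 rose and 4 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.00103, and adjusted p = 0.114 with an estimated correlation). Among them the collagen gene COL1A2 rose from 0.88 ± 0.11 to 627 ± 227 CPM and COL3A1 from 7.07 ± 2.91 to 876 ± 272 CPM. Fitted with only the laggers and the parental line, the count of changed genes was 3482.

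First-passage leaders were compared with the parental line in the same way. NR4A2 rose to 187 ± 27.5 CPM (log2 fold change 10.73 ± 0.39 SE, edgeR adjusted p = 7.74e-11), and KRT7, a keratin of ductal epithelium, from 6.90 ± 2.17 to 503 ± 107 CPM (6.19 ± 0.45, edgeR adjusted p = 1.56e-07). S100A4, a calcium-binding protein linked to cell motility, rose from 124 ± 27.0 to 2544 ± 1520 CPM (4.35 ± 0.38, edgeR adjusted p = 7.15e-07), and PLAT, the tissue plasminogen activator, from 0.50 ± 0.37 to 291 ± 155 CPM (9.12 ± 0.88, edgeR adjusted p = 1.85e-06). UCA1 fell to 2.78 ± 1.76 CPM (-7.05 ± 0.59, edgeR adjusted p = 4.68e-07). In all 7394 genes differed, 3762 higher and 3632 lower, and 5543 of them by a log2 fold change of at least 1.

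Other genes that rose in passage 1 leaders had 0 to 2 parental counts. DPPA3, a germ cell and early embryo gene, was at least 1290-fold higher than in the parental line, AGR2 at least 1200-fold, TMEM45A (26.5 ± 2.25 CPM) at least 937-fold and FAT2 at least 889-fold. EHF, an epithelial transcription factor, was at least 848-fold higher and RAB25, a GTPase of epithelial cells, at least 825-fold, and all 6 genes had 0 parental counts. Without leader replicate 2 RAB25 was at least 234-fold higher, and without replicate 3 AGR2 at least 701-fold. GDF3 reached 77.6 ± 44.9 CPM (ratio 8590, 95% counting interval 1540 to 339000), the lectin ITLN1 75.2 ± 54.3 CPM (7470, 1340 to 295000) and the acetylcholine receptor subunit CHRNA6 110 ± 62.3 CPM (5550, 1530 to 45800). Among genes that fell, GSG1 changed by -8.53 ± 0.99, PEAR1 by -7.37 ± 0.96, ELOVL2 by -7.09 ± 0.77, HKDC1 by -7.06 ± 1.13 and CACNG7 by -6.76 ± 1.09. The apolipoprotein APOA2 was lower by a ratio of 634 (114 to 25100) and CREB3L3 by 253 (69.8 to 2090), and of the PSG family, uncertain as above, PSG9 by 1060 (294 to 8790) and PSG4 at least 161-fold.

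Among gene lists, the stress and YAP target lists kept their calls in passage 1 leaders with an estimated correlation. Of 26 immediate early and stress genes, 20 rose, 1 fell and 5 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 1.69e-20, and adjusted p = 0.0454 with an estimated correlation). FOS changed by 5.73 ± 0.32 and ATF3 by 5.13 ± 0.32. Of 21 YAP and TEAD targets, 15 fell and 6 did not pass (15 fell and 1 rose when adjusted over the list alone, camera adjusted p = 9.34e-06, and adjusted p = 0.0454 with an estimated correlation). AMOTL2 changed by -3.62 ± 0.36 and ASAP1 by -3.28 ± 0.21. Of 44 cell cycle genes, 32 fell and 12 did not pass (33 fell when adjusted over the list alone, camera adjusted p = 7.15e-12, and adjusted p = 0.208 with an estimated correlation). MCM4 changed by -1.87 ± 0.18 and CDC20 by -1.84 ± 0.21. All 13 mitochondrially encoded genes rose, also when adjusted over the list alone (camera adjusted p = 1.03e-18, and adjusted p = 0.133 with an estimated correlation). MT-ND3 changed by 3.61 ± 0.29. Of 35 nuclear genes of oxidative phosphorylation, 22 rose and 7 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0025, and adjusted p = 0.529 with an estimated correlation). NDUFA1 changed by 3.06 ± 0.33. Of 25 epithelial genes, 16 rose, 2 fell and 7 did not pass (17 and 2 when adjusted over the list alone, camera adjusted p = 0.00423, and adjusted p = 0.286 with an estimated correlation). KRT18 changed by 1.91 ± 0.31 and KRT8 by 1.73 ± 0.29, keratins with many pseudogenes. Of 40 actin and motility genes, 19 fell and 10 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.00401, and adjusted p = 0.276 with an estimated correlation). ARHGEF2, an activator of RhoA, changed by -3.20 ± 0.28 and RHOB by 3.32 ± 0.29.

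In the antigen presentation and interferon lists fewer than 50% of the genes rose in passage 1 leaders. Of 25 antigen presentation genes, 12 rose, 1 fell and 12 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.0285, and adjusted p = 0.657 with an estimated correlation; camera adjusted p = 0.0686 without parental replicate 2). HLA-C changed by 1.91 ± 0.31 and B2M, the light chain of class I molecules, by 3.55 ± 0.49. Of 36 interferon response genes, 16 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.00608, and adjusted p = 0.507 with an estimated correlation). OAS1 changed by 2.68 ± 0.38. Of 26 drug efflux and oxidative defence genes, 13 fell and 3 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.00723, and adjusted p = 0.208 with an estimated correlation). TXNRD1 changed by -2.14 ± 0.30. Of 10 fibroblast markers, 6 rose and 2 fell, with the same counts when adjusted over the list alone, COL1A2 reaching 719 ± 260 CPM (9.66 ± 0.58), COL3A1 952 ± 370 CPM (7.08 ± 0.55) and PDGFRA a change of 6.34 ± 0.93 (ratio from counts 83.7, and 49.1 without leader replicate 3; camera adjusted p = 0.00723, and adjusted p = 0.286 with an estimated correlation). COL1A1, which fibroblasts express beside COL1A2, stood at 0.0892% to 16.0% of the COL1A2 level across the 15 injected libraries.

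**Figure D2:**
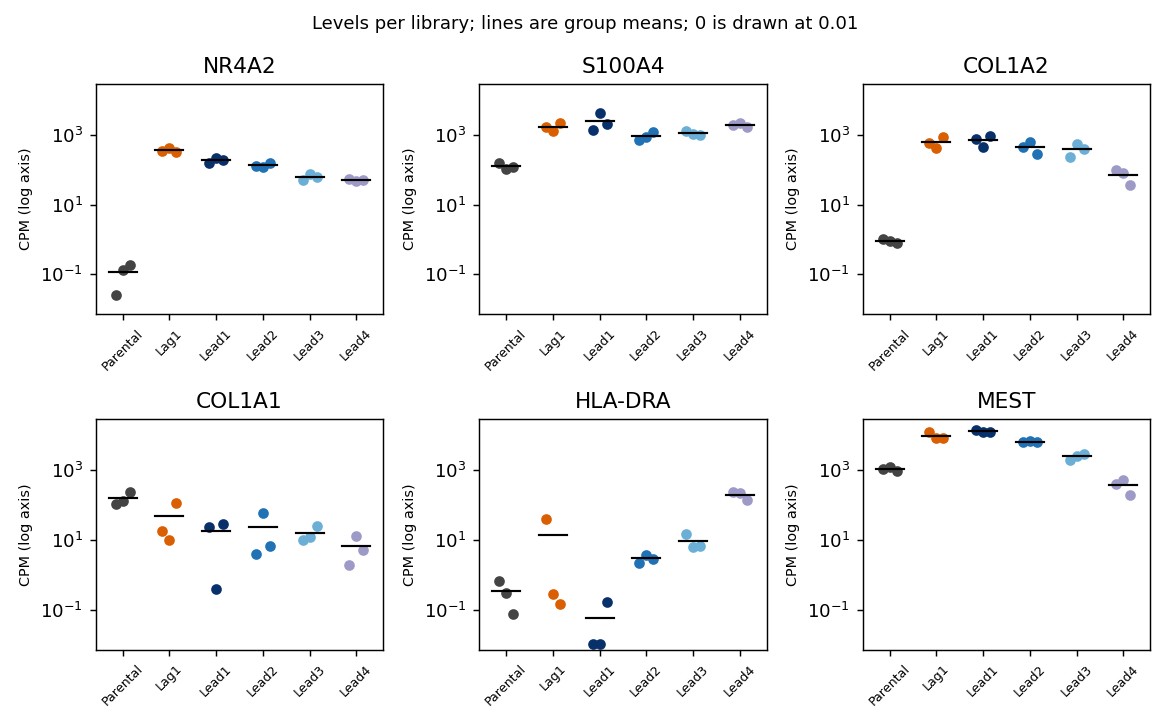
Levels of NR4A2, S100A4, COL1A2, COL1A1, HLA-DRA and MEST in CPM on a log axis, 1 point per library and 3 libraries per group, with a line at each group mean; values of 0 are drawn at 0.01. NR4A2, S100A4 and COL1A2 are higher in all 15 injected libraries than in the parental ones, HLA-DRA reaches 202 ± 53.7 CPM in passage 4 leaders, and MEST falls from 13290 ± 960 CPM in passage 1 leaders to 374 ± 163 CPM in passage 4 leaders.

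Laggers and leaders of passage 1 moved away from the parental line in much the same genes. Of the genes called in both comparisons, 2783 were higher in both, 2462 lower in both and 2 went opposite ways. Independent lists of those sizes would share 809 higher and 647 lower genes. In 10 draws all libraries were simulated without change, the parental ones included, and 0 called genes were shared in each direction (edgeR). Without change few genes are called, so that 0 was near certain in advance. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.901 (0.48 in the simulation), with a covariance of 3.70 against a simulated covariance of 0.189. The difference of 3.51 is the covariance beyond that simulation. Each gene was simulated at its mean over all groups, so noise may be too low for genes near absent from the parental line. The difference therefore does not measure the part free of the shared controls. The 3 parental libraries are too few to split, so part of the excess in the counts of shared genes may come from those controls.

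Leaders of passages 2 and 3 were compared with the parental line to follow the selection. In passage 2 leaders 4846 genes differed (2444 higher, 2402 lower), and in passage 3 leaders 3976 (2230 higher, 1746 lower). Most stress genes were high, with 21 of 26 immediate early and stress genes higher at passage 2 (21 rose and 1 fell when adjusted over the list alone; camera adjusted p = 5.34e-33, and adjusted p = 0.0101 with an estimated correlation) and 18 higher and 1 lower at passage 3 (19 and 1 when adjusted over the list alone; camera adjusted p = 1.04e-26, and adjusted p = 0.0254 with an estimated correlation). Part of the cell cycle genes were low, with 23 of 44 lower at passage 2 (27 when adjusted over the list alone; camera adjusted p = 2e-08, and adjusted p = 0.244 with an estimated correlation) and 21 at passage 3 (22 when adjusted over the list alone; camera adjusted p = 1.91e-07, and adjusted p = 0.397 with an estimated correlation). YAP and TEAD targets were lower for 11 of 21 at passage 2 (1 higher) and 10 at passage 3 (2 higher; 14 and 13 lower, 1 and 2 higher when adjusted over the list alone; camera adjusted p = 1.43e-05 and 8.08e-05, and adjusted p = 0.0542 and 0.0631 with an estimated correlation). All 13 mitochondrially encoded genes were higher at passages 2 and 3, also when adjusted over the list alone (camera adjusted p = 7.82e-18 and 3.39e-16, and adjusted p = 0.145 and 0.136 with an estimated correlation).

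At passages 2 and 3 further lists passed with camera, none of them with an estimated correlation, and in several most members did not pass. Epithelial genes were higher for 11 of 25 at passage 2 (1 lower) and 9 at passage 3 (2 lower; 11 and 12 higher, 1 and 2 lower when adjusted over the list alone; camera adjusted p = 0.000936 and 0.000671, and adjusted p = 0.233 and 0.241 with an estimated correlation). Interferon genes were higher for 15 and 10 of 36 and lower for 1 and 1 (20 and 11 higher, 1 and 1 lower when adjusted over the list alone; camera adjusted p = 3.41e-05 and 0.000671, and adjusted p = 0.233 and 0.418 with an estimated correlation), and antigen presentation genes higher for 12 and 14 of 25 and lower for 1 and 1 (13 and 16 higher, 1 and 1 lower when adjusted over the list alone; camera adjusted p = 0.000936 and 0.000478, and adjusted p = 0.528 and 0.479 with an estimated correlation). Drug efflux and oxidative defence genes were lower for 14 and 15 of 26 and higher for 3 and 2 (14 and 16 lower, 4 and 3 higher when adjusted over the list alone; camera adjusted p = 0.00442 and 4.36e-05, and adjusted p = 0.171 and 0.0538 with an estimated correlation). Fibroblast markers were higher for 4 and 3 of 10 and lower for none (5 and 4 higher, 0 and 1 lower when adjusted over the list alone; camera adjusted p = 0.00443 and 0.00305, and adjusted p = 0.233 and 0.241 with an estimated correlation). The passage 2 count was 3167 without parental replicate 3 and 3188 without leader replicate 3, and the passage 3 count was 2589 without parental replicate 3 and 2491 without leader replicate 1. One passage 3 library, replicate 2, held 394150 counts of the haemoglobin gene HBB, 2.04% of its gene counts.

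Passage 4 leaders, the end of the selection, were compared with the parental line. SERPINA1, the gene of alpha-1-antitrypsin, went from 0.097 ± 0.0931 to 681 ± 211 CPM (log2 fold change 12.63 ± 1.93 SE, edgeR adjusted p = 0.000219), and CHI3L1, a chitinase-like secreted glycoprotein, from 0.187 ± 0.0791 to 914 ± 130 CPM (12.27 ± 1.83, edgeR adjusted p = 0.000175). TINAGL1, a matrix protein that binds laminin and integrins, rose from 0.149 ± 0.0882 to 995 ± 606 CPM (12.72 ± 2.13, edgeR adjusted p = 0.000456); its ratio from counts was 7500, and 4570 without leader replicate 3. ALDH1A1, an aldehyde dehydrogenase, fell from 709 ± 206 to 36.2 ± 16.8 CPM (-4.29 ± 0.35, edgeR adjusted p = 6.82e-07), and SLC7A11, the cystine transporter, from 68.6 ± 22.9 to 2.37 ± 0.90 CPM (-4.86 ± 0.48, edgeR adjusted p = 5.18e-06). In all 4480 genes differed, 2389 higher and 2091 lower, and 3174 of them by a log2 fold change of at least 1.

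Further genes rose in passage 4 leaders from 0 or 1 parental counts. The serine protease gene PRSS22 reached 112 ± 70.1 CPM (ratio 12700, 95% counting interval 2280 to 502000), xanthine dehydrogenase XDH 96.5 ± 32.0 CPM (10200, 1820 to 402000), PLEKHG1 90.4 ± 45.5 CPM (10100, 1820 to 401000) and the class II antigen gene HLA-DQA1 72.7 ± 28.7 CPM (7410, 1330 to 293000). SERPINA5 was at least 1180-fold higher, the cytokine gene IL1B at least 883-fold (28.2 ± 46.0 CPM) and LINC00511 at least 1170-fold, the last uncertain because the kit does not mark strand. Without leader replicate 1 IL1B was at least 58.8-fold higher, and its call was lost with limma-voom. Without replicate 3 the PRSS22 ratio was 7630. Of genes that fell, the phosphatase gene PTPRO was at least 522-fold lower than its parental 19.4 ± 7.81 CPM, GGT5 at least 361-fold and BIRC7 at least 235-fold. ITGBL1 was lower than its parental 64.3 ± 3.40 CPM by a ratio of 4960 (891 to 196000), the chemokine receptor CCR1 by 409 (113 to 3380), the cytokine IL18 by 291 (99.4 to 1410), APOA2 by 227 (77.4 to 1100) and CACNG7 by 477 (85.3 to 18900). PSG5 (ratio 595, 107 to 23500) and PSG9 (-8.39 ± 1.21) fell with the uncertainty given above for that family.

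In the antigen presentation, stress, MAPK output and inflammatory lists more genes were higher than lower in passage 4 leaders against the parental line. Of 25 antigen presentation genes, 18 rose and 7 did not pass (20 rose and 1 fell when adjusted over the list alone, camera adjusted p = 9.43e-12, and adjusted p = 0.211 with an estimated correlation). HLA-C changed by 2.75 ± 0.32 and the class II gene HLA-DRB1 by 8.28 ± 0.93, from 0.63 ± 0.247 to 201 ± 50.2 CPM; reads of HLA genes can be shared between close relatives. CD79A, a B cell receptor component and a member of the leukocyte list, rose beside them from 0.0995 ± 0.0895 to 440 ± 213 CPM (12.00 ± 1.84). Of 26 immediate early and stress genes, 19 rose and 7 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 2.04e-30, and adjusted p = 0.0147 with an estimated correlation). NR4A2 changed by 8.85 ± 0.37 and DUSP1 by 3.47 ± 0.25. Of 25 MAPK output genes, 11 rose and 2 fell (13 and 3 when adjusted over the list alone, camera adjusted p = 0.00885, and adjusted p = 0.374 with an estimated correlation). The call was lost without leader replicate 3 (camera adjusted p = 0.0504). The feedback inhibitor SPRY2 changed by 1.06 ± 0.16. Of 27 inflammatory and NF-kB genes, 13 rose and 2 fell (16 and 2 when adjusted over the list alone, camera adjusted p = 0.0453, and adjusted p = 0.477 with an estimated correlation). TNFAIP3, an inhibitor of NF-kB, changed by 3.28 ± 0.55 (ratio from counts 10.6, and 6.59 without leader replicate 3). Interferon genes were higher for 10 of 36 and lower for 1, with the same counts when adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.573 with an estimated correlation). Mitochondrially encoded genes were higher for 12 of 13 (13 when adjusted over the list alone; camera adjusted p = 1.56e-10, and adjusted p = 0.313 with an estimated correlation). Without leader replicate 1 the inflammatory and interferon lists did not pass (camera adjusted p = 0.135 and 0.0707).

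In the oxidative defence, YAP target and cell cycle lists more genes fell than rose in passage 4 leaders. Of 26 drug efflux and oxidative defence genes, 13 fell and 3 rose (14 and 3 when adjusted over the list alone, camera adjusted p = 6.64e-05, and adjusted p = 0.059 with an estimated correlation). ALDH1A1 and SLC7A11 were among those that fell, and ALDH3A1 rose by 6.25 ± 0.86 (ratio from counts 82.5, and 42.9 without leader replicate 3). Of 21 YAP and TEAD targets, 11 fell and 3 rose (11 and 4 when adjusted over the list alone, camera adjusted p = 6.64e-05, and adjusted p = 0.059 with an estimated correlation). ASAP1 changed by -2.48 ± 0.20 and RBMS3 by -3.64 ± 0.37. Of 44 cell cycle genes, 13 fell, 2 rose and 29 did not pass (15 and 2 when adjusted over the list alone; camera adjusted p = 0.0168, and adjusted p = 0.703 with an estimated correlation; camera adjusted p = 0.0544 without leader replicate 1). CDC20 changed by -1.33 ± 0.20 and MCM4 by -1.10 ± 0.18. Of 20 mesenchymal genes, 7 rose and 3 fell (9 and 3 when adjusted over the list alone, camera adjusted p = 0.0658). S100A4 changed by 3.97 ± 0.37, SPARC by 5.66 ± 0.81 (ratio from counts 47.5, and 19.8 without leader replicate 1) and FN1 by 7.98 ± 1.24. The list did not pass with camera and passed against no change (up, fry adjusted p = 0.00254). Of 10 fibroblast markers, 3 rose and 1 fell, with the same counts when adjusted over the list alone, and the list did not pass (camera direction up with adjusted p = 0.0754, while its median was -0.729), though it passed against no change (up, fry adjusted p = 0.00643). COL1A2 rose by 6.31 ± 0.52, and COL1A1 changed by -4.59 ± 1.32, a call that was lost without passage 4 replicate 1 or 3.

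**Figure D3:**
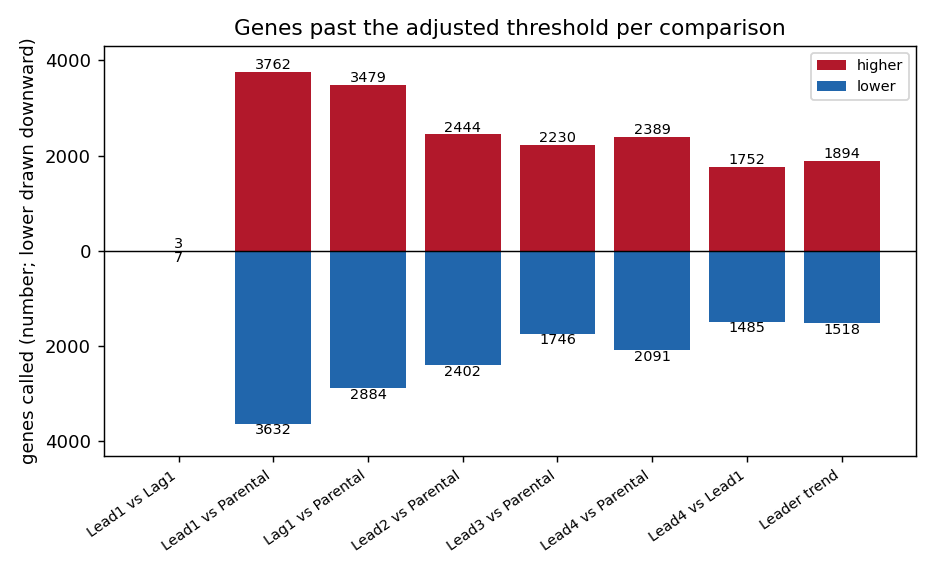
Number of genes called higher and lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05) in each of the 8 comparisons, with bars from 0 upward for higher and downward for lower genes. Passage 1 leaders against laggers give 10 genes, and each injected group against the parental line gives 3976 to 7394.

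Change across the 4 leader passages was tested as a linear trend, in log2 per passage. HLA-DRA, a class II antigen presentation gene, went from 0.0554 ± 0.0959 CPM at passage 1 to 2.95 ± 0.778, 9.51 ± 4.99 and 202 ± 53.7 CPM at passages 2, 3 and 4 (trend 3.68 ± 0.58 SE, edgeR adjusted p = 0.000488), and XDH from 0.108 ± 0.128 to 1.41 ± 0.579, 9.06 ± 6.61 and 96.5 ± 32.0 CPM (3.18 ± 0.30, edgeR adjusted p = 5.27e-06). SEMA6B, a semaphorin of axon guidance, rose from 2.61 ± 0.943 to 295 ± 149 CPM (2.36 ± 0.21, edgeR adjusted p = 3.19e-06). VEGFA, the vascular growth factor, rose from 53.4 ± 6.86 to 388 ± 188 CPM (0.98 ± 0.10, edgeR adjusted p = 1.58e-05). ACKR3, a scavenging receptor for the chemokine CXCL12, fell from 199 ± 139 to 1.98 ± 1.06 CPM (-2.30 ± 0.22, edgeR adjusted p = 5.63e-06).

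The trend called 3412 genes, 1894 rising and 1518 falling, and passage 4 against passage 1 called 3237 genes (1752 higher, 1485 lower). Of the trend genes, 2145 changed by at least 1 log2 unit over the 3 steps, 984 rising and 1161 falling. With offsets for GC content and length the trend called 1451 rising and 1446 falling genes, so the balance is not settled. The ectoenzyme gene ENPP3 rose to 24.7 ± 6.02 CPM at passage 4, at least 585-fold above passage 1. HLA-DQA1 rose by 3.20 ± 0.34 and CD79A by 3.50 ± 0.54 per passage. From 0 counts at passage 1 PRICKLE2 rose at least 111-fold, ZP4 at least 226-fold, KLHL4 at least 122-fold and SPRR2D at least 144-fold, while TENM2 rose by a ratio of 574 (95% counting interval 158 to 4740). DPPA3 fell by a ratio of 2790 (501 to 110000) and ITGBL1 by 1020 (183 to 40400). CALML3 was at least 226-fold lower at passage 4, FBLN2 at least 225-fold, PTPRO at least 205-fold, IP6K3 at least 173-fold, WFIKKN2 at least 154-fold, FCER2 at least 146-fold, DNASE1L3 at least 146-fold and KIAA1210 at least 111-fold. Without the library that held most of its counts, the rise was at least 21.9-fold for PRICKLE2, 58.5-fold for ZP4, 67.4-fold for KLHL4 and 37.5-fold for SPRR2D, and a ratio of 120 for TENM2. In the same way the fall was at least 112-fold for CALML3, 75.0-fold for IP6K3, 91.2-fold for WFIKKN2, 95.2-fold for FCER2 and 19.4-fold for KIAA1210, and a ratio of 595 for ITGBL1. CALML3, WFIKKN2, FBLN2 and IP6K3 lost their calls with limma-voom. FBLN2 lost its call without any 1 of 8 leader libraries and IP6K3 without passage 2 replicate 1, and without passage 4 replicate 3 the trend called 1740 genes and passage 4 against passage 1 called 1512 (2113 without passage 1 replicate 3).

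Across the leader passages 11 lists passed with camera and none with an estimated correlation. In the cell cycle, motility, antigen presentation and MAPK output lists fewer than 50% of the genes rose. Of 44 cell cycle genes, 21 rose and 23 did not pass (27 rose when adjusted over the list alone, camera adjusted p = 1.74e-11, and adjusted p = 0.264 with an estimated correlation). UBE2C changed by 0.51 ± 0.051 and MKI67 by 0.54 ± 0.066 per passage, from 85.3 ± 9.14 to 232 ± 35.2 CPM. Of 40 actin and motility genes, 18 rose and 22 did not pass (19 rose when adjusted over the list alone, camera adjusted p = 6.83e-06, and adjusted p = 0.227 with an estimated correlation). The actin crosslinker ACTN4 changed by 0.92 ± 0.093 and VCL by 0.47 ± 0.066. Of 25 antigen presentation genes, 12 rose and 13 did not pass (14 rose and 1 fell when adjusted over the list alone, camera adjusted p = 1.92e-05, and adjusted p = 0.375 with an estimated correlation). HLA-DRB1 changed by 1.69 ± 0.25, HLA-DMB by 1.28 ± 0.19 and CIITA, the activator of class II genes, by 2.48 ± 0.41. Of 25 MAPK output genes, 12 rose and 1 fell (13 and 1 when adjusted over the list alone, camera adjusted p = 2.43e-05, and adjusted p = 0.264 with an estimated correlation). FOSL1, an AP-1 component, changed by 1.30 ± 0.19. Of 27 inflammatory and NF-kB genes, 9 rose and 2 fell (10 and 2 when adjusted over the list alone, camera adjusted p = 0.0295, and adjusted p = 0.452 with an estimated correlation; camera adjusted p = 0.138 without passage 4 replicate 1). IRAK2 changed by 0.87 ± 0.15.

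All mitochondrially encoded genes fell across the leader passages, as did a minority of the epithelial, lipid synthesis and protein folding genes. Of 25 epithelial genes, 9 fell and 16 did not pass (11 fell and 2 rose when adjusted over the list alone, camera adjusted p = 0.00302, and adjusted p = 0.264 with an estimated correlation). CLDN1 changed by -0.75 ± 0.079 and the junction protein JUP by -0.65 ± 0.12. All 13 mitochondrially encoded genes fell, also when adjusted over the list alone (camera adjusted p = 5.34e-10, and adjusted p = 0.264 with an estimated correlation). MT-CO1 changed by -0.60 ± 0.087. Of 35 nuclear genes of oxidative phosphorylation, 7 fell and 1 rose (9 and 1 when adjusted over the list alone; camera adjusted p = 0.00171, and adjusted p = 0.539 with an estimated correlation). Of 29 cholesterol and fatty acid synthesis genes, 8 fell and 2 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.000926, and adjusted p = 0.264 with an estimated correlation). HSD17B7 changed by -0.45 ± 0.068. Of 30 genes of the integrated stress and unfolded protein response, 6 fell and 1 rose (7 and 1 when adjusted over the list alone, camera adjusted p = 0.0121, and adjusted p = 0.264 with an estimated correlation; camera adjusted p = 0.0503 without passage 1 replicate 1). HERPUD1 changed by -0.69 ± 0.066 and XBP1 by -0.47 ± 0.054. Of 10 fibroblast markers, 5 fell and 5 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.0253, and adjusted p = 0.328 with an estimated correlation; camera adjusted p = 0.0602 without passage 1 replicate 3). COL1A2 changed by -1.03 ± 0.13, and the proteoglycan gene LUM was lower at passage 4 than at passage 1 by a ratio of 159 (95% counting interval 43.7 to 1320). The same 11 lists passed, in the same direction, between passage 4 and passage 1.

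Many genes that changed at passage 1 in laggers then moved the other way across the leader passages, 2 comparisons that share no library. Laggers and the first of these leaders come from the same passage, so the 2 comparisons are not independent. An effect common to passage 1, such as one of harvest or preparation, cannot be told apart from a return toward the parental line. Of 2188 genes called in both, where independent lists would share 1341, 1998 (91.3%) moved in opposite directions and 190 in the same direction. NR4A2, up in laggers, fell by 0.67 ± 0.077 per passage, and FOSL1, down in laggers at -4.19 ± 0.62, rose. Genes with opposite changes from the parental line at the ends of the series included MEST, an imprinted gene chosen after its values were seen whose pseudogenes make its count uncertain: it averaged 1115 ± 131 CPM in the parental line, 13290 ± 960 CPM in passage 1 leaders and 374 ± 163 CPM in passage 4 leaders (trend -1.69 ± 0.096, edgeR adjusted p = 8.81e-08). In the 4 comparisons of leaders with the parental line, 1299 genes were higher and 1094 lower each time, against 11.5 and 7.51 for independent lists and 0 for simulated unchanged groups (edgeR). Simulated groups without change give few calls, so that 0 was near certain in advance. Nor are the 4 comparisons independent: they share the parental libraries, and each passage was grown from the one before.

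Lists tied to nerve invasion did not pass with camera, which ranks a list against the other genes. Of 23 nerve-invasion ligands and receptors, 8 rose and 2 fell in passage 1 leaders against the parental line, with the same counts when adjusted over the list alone (camera adjusted p = 0.363), with the chemokine receptor CXCR4 up from 3 parental counts by a ratio of 138 (95% counting interval 46.7 to 673), the neurotrophic factor GDNF at least 139-fold (67.8 and at least 78.2-fold without leader replicate 2) and LIFR up by 2.84 ± 0.56. Of 44 axon guidance genes, 8 rose and 14 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.337), with EPHA2 at -2.60 ± 0.29 and NEO1 at 2.20 ± 0.27. Of 26 integrins and laminins, 8 rose and 6 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.705), with ITGA6 at 4.14 ± 0.53 and LAMA4 at -6.22 ± 0.86. Of 33 matrix proteases and inhibitors, 6 rose and 13 fell (7 and 13 when adjusted over the list alone; camera adjusted p = 0.248), with PLAT up and MMP17 at -4.61 ± 0.78, and across the leader passages the urokinase receptor PLAUR rose by 1.24 ± 0.21 and MMP10 by 1.71 ± 0.35 per passage. Of 20 mesenchymal genes, 8 rose and 3 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.248), with FN1 at 7.30 ± 1.21 and the collagen crosslinker LOXL2 at -1.99 ± 0.36. With fry, which tests a list against no change, nerve-invasion genes (up, fry adjusted p = 0.00505), mesenchymal genes (up, 0.00398) and matrix proteases (down, 0.00195) passed. Axon guidance genes (fry adjusted p = 0.222) and integrins and laminins (0.156) did not.

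Several further lists did not pass with camera in passage 1 leaders against the parental line. Of 24 TGF-beta targets, 4 rose and 5 fell (4 and 4 when adjusted over the list alone; camera adjusted p = 0.795), with PMEPA1 at 3.30 ± 0.52, a gene that rose further by 1.18 ± 0.16 per passage (passage 4 to passage 1 ratio from counts 13.9, and 9.12 without passage 4 replicate 3). Of 22 Notch and Wnt targets, 5 rose and 8 fell (6 and 10 when adjusted over the list alone; camera adjusted p = 0.383), with HES1 at 3.76 ± 0.36. Of 36 hypoxia and glycolysis genes, 10 rose and 8 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.645), with the peptide hormone ADM at 6.96 ± 0.53. Of 29 cholesterol and fatty acid synthesis genes, 13 rose and 8 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0952), with FDFT1 at 1.30 ± 0.15. Against no change, cholesterol and fatty acid synthesis passed (up, fry adjusted p = 0.00195), and TGF-beta targets (0.746), Notch and Wnt targets (0.26) and hypoxia and glycolysis (0.11) did not.

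Markers of other cells that a nerve harvest could hold were mixed in passage 1 leaders against the parental line. Of 6 Schwann cell markers, 2 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.823), with EGR2, also a stress gene, at 6.07 ± 0.74. Of 8 macrophage and leukocyte markers, 3 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.751), with CTSS at least 252-fold (at least 78.2-fold without leader replicate 2) and PTPRC at least 74.9-fold higher. Of 10 endothelial and mural markers, 2 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.751), with RGS5 at 5.28 ± 0.77 (ratio from counts 34.8, and 22.1 without leader replicate 2). Of 4 muscle, fat, nerve and blood markers, 2 rose and 2 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.337), among them TNNT3 by a ratio of 3470 (95% counting interval 623 to 137000), and 2050 without leader replicate 3. This last list passed against no change (up, fry adjusted p = 0.00481), and Schwann cell (0.141), macrophage and leukocyte (0.156) and endothelial and mural markers (0.219) did not.

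Genes of chromosome 6 were higher as a set in every injected group than in the parental line. In passage 4 leaders the median log2 fold change of 383 expressed chromosome 6 genes exceeded that of 7470 genes on other chromosomes by 0.62. The 95% bootstrap interval over genes, without spread between libraries, was 0.53 to 0.69. The next chromosome, 13, stood at 0.25. The excess was 0.39 in passage 1 leaders, 0.41 in laggers, 0.48 in passage 2 and 0.55 in passage 3 leaders. Of the 383 genes, 144 were called higher and 7 lower at passage 4, so 37.6% were higher against 12.4% of genes elsewhere; at passage 1, 112 were called higher and 72 lower. With offsets for GC content and length the excess in passage 1 leaders was 0.38, below the 0.393 of chromosome 13. At passage 4 all 14 windows of 10 Mb along chromosome 6 had a median above that of the other chromosomes. The pattern was noticed after the values were seen, and it includes the HLA genes named above.

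**Figure D4:**
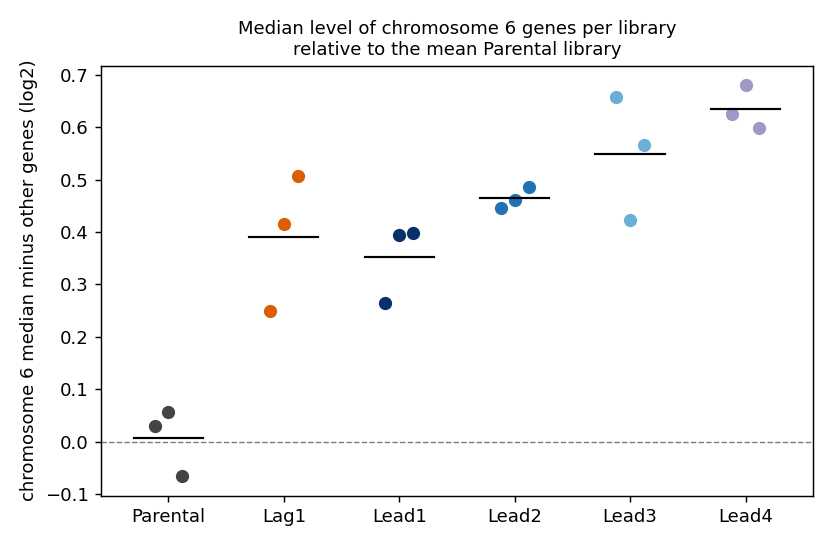
Median level of chromosome 6 genes minus that of genes on the other chromosomes (log2, relative to the mean parental library, trend with GC content and length removed), 1 point per library, 3 libraries per group, with a line at each group mean. The 15 injected libraries lie at 0.249 to 0.680 and the 3 parental libraries at -0.066 to 0.0559.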

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

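The tests of the HLA region, of the spread between libraries, of other cell types, of nerve fibroblasts, of stress and of the HBB reads were chosen only after the result was seen. The tests of library depth and of other splits of the libraries were planned before. The offsets for GC content and length were added, and the chromosome 6 pattern noticed, after the data were seen.

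Passage 1 leaders and laggers, each set against the parental line, differed from one another in 10 genes by a direct test. HSPA6, BAG3 and AMOTL2 were among the 7 that were lower in leaders, and AGR2 was among the 3 that were higher. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05; the real split, 1 of 10, called 10 genes and the highest other split 5. For the 5 comparisons with the parental line the splits are equally few, and the highest other split called 0 genes with edgeR in each, against real values of 6363 for laggers and 7394, 4846, 3976 and 4480 for leaders of passages 1, 2, 3 and 4.

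Passage 4 and passage 1 leaders, each set against the parental line, differed in 3237 genes by a direct test. The highest of the other splits of these 6 libraries called 1 gene, and 10 splits are again too few for a share under 0.05. For the trend over 4 passages, 1 of 100 splits, the real one, called as many as 3412 genes, a share under 0.05, and the highest other called 523. These splits moved single libraries between passages and so broke up replicates that resemble each other. They cannot show whether the order of whole passages could arise by chance. In 26 genes the change from the parental line was upward at passage 1 and downward at passage 4, with the difference itself called. They include MEST, ACKR3 and CCDC73, the last at 4.77 ± 0.587 and then -2.74 ± 0.675. In 59 genes the order was downward and then upward, among them SEMA6B, PLAUR, CDCP1, KCNN4 and PTPRU.

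Entries that the comparisons do not use also parted the groups. In 15 injected libraries, which is all of them, a larger share of reads aligned to more than one place than in every parental library, up to 32.6% in lagger replicate 3. In 6 injected libraries the unaligned share was above that of every parental library, up to 24.8% in passage 3 leader replicate 2. Groups of 3 libraries were not tested for single libraries that stand apart.

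Genes of chromosome 6 were higher in all injected groups, with an excess over the other chromosomes of 0.618 in passage 4 leaders against the parental line. With offsets for GC content and length the excess was 0.649, above the bound of 0.309 set for it. Its 95% bootstrap interval over genes, not libraries, was 0.556 to 0.721. These values argue against such bias as the whole cause at passage 4. At passage 1 the corrected values were 0.38, 0.393 for chromosome 13 and -0.429 for chromosome 22, so chromosome 6 did not stand alone. Outside the HLA region, 25 to 35 Mb, the excess was 0.642 (interval over genes 0.556 to 0.759), which argues against HLA genes alone. The lowest of the 15 injected libraries stood at 0.249 against 0.0559 for the highest parental one, which argues against the spread between these libraries. The mean of the parental libraries sets 0 here, and they can be technical repeats, so spread between separate cultures is not covered. Selection during injection for cells with more copies of chromosome 6, or their presence in the starting culture of the injected cells, may underlie it. This hypothesis was not tested, since no DNA was analysed.

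The distance of the injected groups from the parental line, 7394 genes in passage 1 leaders, stayed at 7561 with offsets for GC content and length and at 7029 after thinning to the smallest gene total, which argues against these as the whole cause; thinning leaves other library measures, such as the mitochondrial share, as they were. RNA of other cells would need to make up 87.5% of a library to lower a gene 8-fold, and 120 genes of at least 10 CPM fell that far in passage 1 leaders while KRT8 and KRT18 of the line rose by 1.73 ± 0.29 and 1.91 ± 0.31, which argues against other cells for the genes that fell. COL1A1 was at most 16.0% of COL1A2 in the injected libraries, where nerve fibroblasts would bring the 2 collagens together. Other fibroblast markers rose with COL1A2 in laggers against the parental line. The ratio was 341 for APOD and 69.4 for LUM (32.6 without lagger replicate 1). DCN went from at most 0.562 CPM to 4.97 to 12.0 CPM. In passage 2 leaders DCN was at most 0.334 CPM, while COL1A2 stood at 287 to 636 CPM. The markers point both ways, so fibroblasts remain open for COL1A2 and COL3A1. How RNA of the host nerve would count at each collagen gene was not tested. For the other genes that rose, other cells remain open as well. Stress of recovering cells cannot be told apart from injection, because the design holds no recovered but unselected group and the time of RNA extraction relative to harvest is not given; the lowest median log2 fold change of the immediate early and stress list over the 5 recovered groups was 1.96. The biological difference in the design, passage through the nerve, remains open as well.

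Passage 3 leader replicate 2 held 394150 counts of HBB where the other 17 libraries held 9 to 33, and 567 counts of its close relative HBD where the others held 0. Blood would bring alpha-globin, and HBA1 and HBA2 together had 1 count there, at most 0.0014% of HBB by the 95% interval for counting error. Reads that align to both HBA1 and HBA2 are not in these counts. As far as reads placed at 1 gene can tell, this argues against blood in the harvest. Foreign nucleic acid that carries HBB sequence could leave such reads. The 24.8% of entries unaligned in that library, against 4.09% to 16.5% in the others, had been seen before and cannot test it, so this explanation stays open. No biological explanation was tested.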

How the results depend on the processing

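Offsets for GC content and length, the library with the largest unaligned share left out of each group, and mitochondrially encoded genes left out were settings chosen only after the data were seen; the others were planned. No named gene, and no gene list called with camera, reversed direction in any setting in which it was tested. Other changed genes were not read for this. The balance of higher and lower genes did turn over in some comparisons. In passage 4 leaders against the parental line 2389 genes were higher and 2091 lower. With offsets for GC content and length these were 2005 and 2242. For passage 4 against passage 1 leaders, 1752 and 1485 became 1324 and 1441 with the same offsets.

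The comparison of passage 1 leaders with laggers depended on the method. Its 10 genes became 372 with DESeq2 (191 higher, 181 lower, all 10 among them), 27 with limma-voom (9 shared), 257 with no filter on low counts (10 shared), 0 with edgeR when only the compared groups were fitted (1289 at an unadjusted p under 0.05), 3 with the replicate block and 1 with offsets for GC content and length. It was 9 with median-ratio normalization, 9 with the stricter filter, 14 after thinning, 11 without the libraries of largest unaligned share (3 shared) and 8 without mitochondrial genes. In the simulated data 19% of the DESeq2 calls were false against 2.1% for edgeR; fitting only the compared groups leaves fewer libraries to estimate the spread, and for the other settings the cause was not tested. The other count that moved by more than 1.5 times was that of laggers against the parental line, 3482 when only those groups were fitted.

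With 1 library left out, which leaves groups of 2, the counts ranged from 0 to 52 for passage 1 leaders against laggers (0 with edgeR without lagger replicate 2, with 2210 at an unadjusted p under 0.05), 5257 to 6392 for laggers against the parental line, and 5971 to 6903, 3167 to 4414, 2491 to 3761 and 2996 to 4045 for leaders of passages 1, 2, 3 and 4. Passage 4 against passage 1 ranged from 1512 to 2821 and the trend from 1740 to 3255. The cause was not tested.

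The replicate block gave 7123, 6124, 4560, 3742, 4198, 2925 and 3113 genes for passage 1 leaders and laggers, passages 2, 3 and 4 against the parental line, passage 4 against passage 1 and the trend. Residuals of libraries with the same number correlated at a mean r of -0.0142 over 45 pairs and those with different numbers at 0.00824 over 90 pairs. Single pairs reached 0.401 and 0.414. The means show no pairing by number over all groups together. Whether leaders and laggers of passage 1 with the same number are paired was not tested on its own.

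Of the named genes, 4846 results kept their call over the settings and 94 lost it. IL1B in passage 4 leaders and CALML3, WFIKKN2, FBLN2 and IP6K3 in the trend lost it with limma-voom. With 1 library left out, 3518 kept their call and 148 lost it. Of the 77 calls of gene lists by camera, 6 held with an estimated correlation: immediate early and stress genes in all 5 comparisons with the parental line and YAP and TEAD targets in passage 1 leaders. fry, which tests a list against no change and so is another question than that of camera, did not pass 8 of the 77: all 7 of leaders against laggers (fry adjusted p = 0.0515 to 0.152) and cell cycle genes in passage 4 leaders (fry adjusted p = 0.0755). Of the 7 camera calls between leaders and laggers, 5 were lost when 1 compared library was left out, a step added after the data were seen, as were 4 of 9 in passage 4 leaders and 3 of 11 in the trend. fry passed 1 list between leaders and laggers that camera did not. At this depth 16% of 2-fold changes between leaders and laggers were found in simulated data, so a gene that did not pass is not shown to be unchanged.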

Other observations

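The comparison of laggers with the trend was chosen only after the result was seen. Genes that changed in laggers and genes that changed across the leader passages moved against each other: 974 rose in laggers and then fell over the leader passages, and 1024 fell and then rose, out of 2188 called in both. Across genes the log2 fold changes of the 2 comparisons, which share no library, had r = -0.394 and a Spearman correlation of -0.475. Levels of FOSL1 show the pattern, with 214 ± 48.7 CPM in the parental line, 11.8 CPM in laggers, 9.63 ± 6.96 CPM in passage 1 leaders and 131 ± 57.9 CPM in passage 4 leaders. UCA1 did not return: it stood at 366 ± 19.7 CPM in the parental line and 1.90 ± 0.302 CPM in passage 4 leaders.

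Passage 1 and passage 4 leaders, set against the same 3 parental libraries, shared 1716 genes that were higher in both and 1594 that were lower in both, where independent lists would share 555 and 469, and 85 genes went opposite ways. The log2 fold changes had r = 0.708 against 0.493 in simulated unchanged groups, and a covariance of 2.64 against 0.193. The difference of 2.45 is the covariance beyond that simulation. With the limit given above for such simulated values, it does not measure the part free of the shared controls. The 3 parental libraries cannot be split, so part of the excess in the counts of shared genes may come from those controls.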
